A study of Mus musculus with 2 samples.

How the data were processed

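Total RNA from back skin was labelled with biotin and hybridised to 1-colour oligonucleotide arrays, per the labels. The series holds 2 arrays, 1 for transgenic mice with a constitutively active AhR in keratinocytes and 1 for wild-type mice, both at an age of 10 days. The genotype of each array was taken from the source names in the labels. The labels do not say whether an array holds 1 animal or a pool, and they give no batch, slide or date.

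The deposited values are linear signal intensities, 1 per probe set, that are never negative. The trimmed mean of the deposited intensities, leaving out the highest and the lowest 2%, was 100.03 on both arrays, so the values had been scaled before deposit. The software that made them is not given in the sources used here, and no detection calls were used here. Scanner files were not used here. Of the 22690 probe sets, 64 were controls. Of the other 22626, 20380 had 1 gene in the platform annotation of 2016, 691 had several and 1555 had none. Only probe sets with 1 gene were named. Their symbols were updated through the gene identifier in a gene table of the mouse assembly GRCm38.p6, in which 29 of the probe sets with 1 gene were not found and kept the annotation's symbol. That table served for names and for the order of neighbouring genes only, and no coordinates are given.

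The signals were scaled again to equal 2% trimmed means, which changed them very little, then raised to a floor and put on the log2 scale. The floor was the 40th percentile of all non-control signals of both arrays, 34.7. Above it lay 59.7% of the probe sets on the transgenic array and 60.2% on the wild-type array. A gene was represented by its probe set with the highest summed signal, which mattered for the 4956 genes with more than 1. A gene counted as measured when that probe set lay above the floor on at least 1 array. The value compared is the log2 ratio of transgenic over wild-type signal. Where 1 array lay at the floor the ratio is a bound and is given as "at least" for a higher and "at least" or "at most" for a lower gene. Genes were called at a 2-fold difference. Of the 202 higher genes 40 were bounds, and of the 97 lower genes 21 were. The scaling left the median log2 ratio of measured genes at -0.05.

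With 1 array per group there is no replicate error, no test and no p-value, and the number of arrays limits the precision. As a technical measure, the spread of log2 ratios between 2 probe sets of a gene was taken. The hybridisation controls gave another, 12 spike-in probe sets with log2 ratios from -0.29 to 0.07, and the 6 probe sets of the dimmest spike-in read 0.300 to 14.0, below the floor. Of the 32 gene lists, 4 were main lists (AhR target genes, cornified envelope and late differentiation, inflammatory cytokines and chemokines, cell cycle) and 15 held markers of cell types that skin can contain. All of them were fixed before the data were examined, as were the floor, the call, all but 1 of the alternatives and the rule for naming genes. Each list's median was set among the medians of 10000 random lists of the same size, drawn from measured genes in 20 bins of mean log2 signal. This percentile describes these 2 arrays and is not a test across animals. The medians of 19 lists lay outside the central 95% of their random lists.

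The genes named are the 12 highest and the 12 lowest log2 ratios among called genes, every measured AhR target, Ahr, the 2 highest and 2 lowest members of each other list (fewer are spelled out where a list is summarised), Xist and Y-linked genes. Genes outside this rule are said to be so where they appear, except Cyp1a2, Ahrr and Cd207, which are named because they lay below the floor. The sets of Lce1, Sprr, C1q, MHC class II and CD3, CD4 and CD8 genes and the epidermal differentiation complex were singled out after the values were seen.

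The calculation was tested on simulated arrays built from the mean signals of both arrays with a noise SD of 0.25 on the log2 ratio. Of 50 genes made 3-fold higher 98.0% were called, and of 50 made 3-fold lower 94.0%. Of 50 made 2-fold higher 34.0% were called, with a median log2 ratio of 0.883, and of 50 made 2-fold lower 48.0%, with a median of -0.985. None of 8434 unchanged genes was called. Of 100 random lists with no shift 4.0% fell outside the central 95%. The simulated noise was independent between probe sets and of the same size at every signal. On the real arrays the log2 ratios of genes above the floor on both had an SD of 0.423, real differences included. The simulated rates therefore check the calculation and are not error rates of these 2 arrays.

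The alternatives were the values as deposited, log2 ratios centred on their median, quantile normalization, lowess centring on signal (span 0.4), floors at the 20th and 60th percentiles, a pseudocount of 16 in place of the floor, the mean over a gene's probe sets, leaving out suffixed probe sets (those whose name carries any letter suffix), and limits of 1.5-fold and 3-fold. A further alternative, chosen after seeing the data, left out the probe sets that can cross-hybridise, whose suffix marks probes shared between genes or possible binding of related transcripts, and kept those whose suffix marks several transcripts of 1 gene. Intervals in the closing section are 95% bootstrap intervals over genes (10000 draws, 2000 for the rank correlation); genes are not independent replicates, so they describe the lists and not animals. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.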

Results

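Gene expression was measured in the back skin of 10-day-old mice. The animals carried either a constitutively active form of the aryl hydrocarbon receptor (AhR) in their keratinocytes or no transgene. AhR is a ligand-activated transcription factor that senses dioxins and related aromatic compounds and induces enzymes of xenobiotic metabolism. The active form signals without a ligand, so the comparison asks which transcripts of whole skin differ when the receptor is switched on in the epidermis. Biotin-labelled total RNA was hybridised to 1 array per genotype, 2 arrays in all, and the labels do not say how many animals each array holds. Without replicates no difference could be tested, and the values below compare these 2 arrays only. Each array gave 22690 probe set signals, from 0 to 4995 on the transgenic array and from 0 to 4587 on the wild-type array. The median signals were 49.1 and 50.7. Of the 12393 genes that could be named, 8894 had a signal above the floor of 34.7 on at least 1 array and 7972 on both. Across 12679 probe sets above the floor on both arrays, the log2 signals correlated with Pearson's r = 0.952, a value across probe sets, which are not independent replicates.

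The xenobiotic enzyme Cyp1a1, keratins and other alarm genes of stressed epidermis, and the chemokine genes Ccl6 and Ccl8 were among the highest on the transgenic array relative to wild type. Cyp1a1 read 1802 against 40.8, 44.2-fold higher. Stfa3, a cysteine protease inhibitor of the stefin A family, was at least 40.1-fold higher (1390 against a wild-type signal below the floor), and Krt6b, a keratin of wounded and hyperproliferative epidermis, was 35.1-fold higher (1450.5 against 41.3). Genes of hair, pigment cells and muscle were lower on the transgenic array as groups, by smaller amounts. In all, 202 genes were at least 2-fold higher and 97 at least 2-fold lower, and 87.9% of the genes above the floor on both arrays lay within 1.5-fold.

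**Figure D1:**
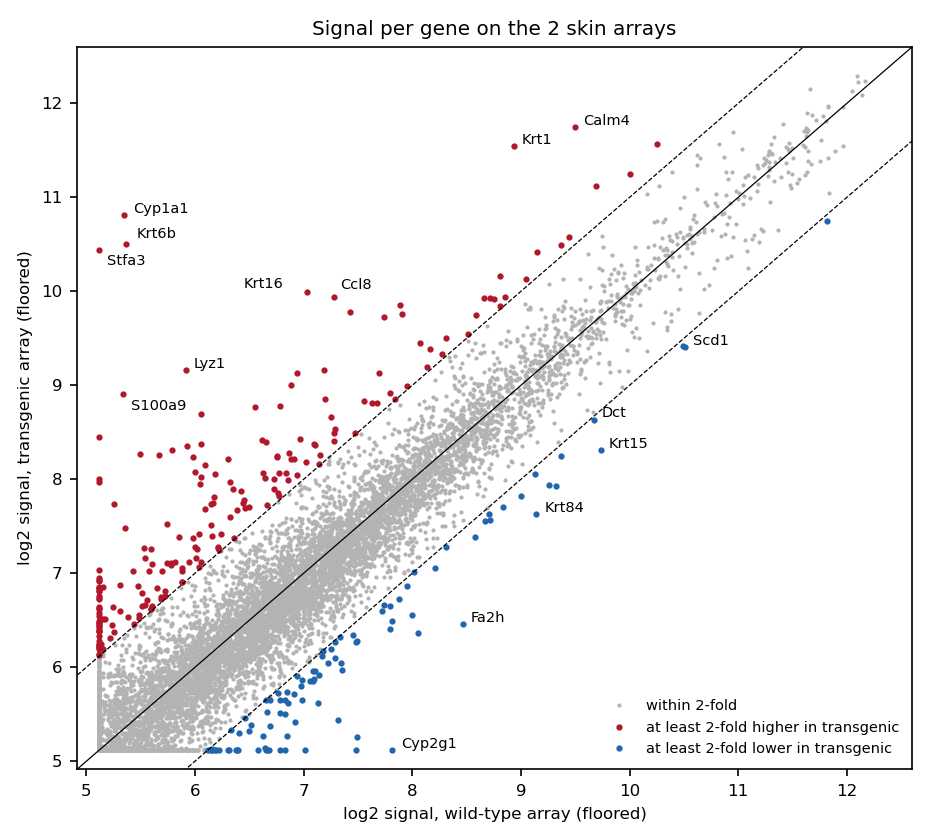
Log2 signal of each gene on the wild-type array (horizontal axis) and on the transgenic array (vertical axis), with signals below the floor set to the floor. The solid line marks equal signal and the dashed lines a 2-fold difference; 202 genes lie on or above the upper dashed line and 97 on or below the lower one.

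Epidermal stress genes and chemokines made up most of the other genes at the top of the list. S100a9, a subunit of the neutrophil and keratinocyte alarmin calprotectin, was 11.9-fold higher. The gene 2610528A11Rik was at least 10.1-fold higher. Krt16, the keratin partner of Krt6, was 7.79-fold higher, Casp14, a protease of the cornifying epidermis, at least 7.39-fold, Hrnr, the gene of the cornified-layer protein hornerin, 6.83-fold, and Epgn, an epidermal growth factor receptor ligand, 6.22-fold. The chemokines Ccl6 and Ccl8 were at least 7.21-fold and 6.31-fold higher. Lyz1, a lysozyme gene, was 9.48-fold higher by its brightest probe set, but the name of that probe set marks possible binding of related transcripts, and the probe set without such a mark gave a log2 ratio of 0.04.

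At the other end, Cyp2g1, a cytochrome P450, was at least 6.50-fold lower (19.0 against 226). Mfap4, a microfibril-associated matrix protein, was 4.70-fold lower. Fa2h, which makes 2-hydroxylated fatty acids for sphingolipids, was 4.02-fold lower, and Sptssb, a small subunit of the first enzyme of sphingolipid synthesis, was 3.22-fold lower. Tlcd4 was 3.67-fold lower, Dpp4, a cell-surface peptidase, at least 3.29-fold, Lce3c, a late cornified envelope gene, at least 3.18-fold, and Ccdc186 2.99-fold. The other probe set of Dpp4 lay below the floor on both arrays (3.0 and 3.9), and the 1 probe set of Lce3c carries the same mark as that of Lyz1. Hamp2, a hepcidin gene, was at least 5.16-fold lower by a probe set with this mark, while its other probe set lay below the floor on both arrays (9.9 and 15.7). Sec24b (at least 3.72-fold), Itsn1 (at least 2.96-fold) and Ilf2 (at least 2.92-fold) each fell under a 2-fold difference when their measured probe sets were averaged. The only other measured probe set of each went the other way, with log2 ratios of 0.28, 0.20 and 0.26. Their probe sets therefore disagree on the direction.

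The known AhR target genes were higher as a group. Of 11 measured members, 5 were at least 2-fold higher, none was at least 2-fold lower, and the median log2 ratio was 0.998. Random lists of the same size and brightness had medians from -0.27 to 0.20 in their central 95%. After Cyp1a1, the highest were Cyp1b1, a hydroxylase of steroids and polycyclic hydrocarbons (3.96-fold, 847 against 214), and Aldh3a1, an aldehyde dehydrogenase (3.44-fold). Nqo1, a quinone reductase, was at least 2.41-fold higher, and Tiparp, an ADP-ribosyltransferase that restrains AhR, 2.20-fold. Xdh, which makes uric acid, read 151 against 75.4 (log2 ratio 0.998, just under the limit). Nfe2l2, the gene of the antioxidant regulator Nrf2, had a log2 ratio of 0.86 and Gsta4, a glutathione transferase, of at least 0.56. Gsta2 (0.13) and Scin (0.03) read nearly the same on both arrays, and Ero1a, an oxidase of the endoplasmic reticulum, was lower (-0.46). Cyp1a2 and Ahrr lay below the floor on both arrays. With the floor at the 60th percentile Nqo1 was at 0.24, and Tiparp was 0.88 without probe sets that can cross-hybridise. Both measured probe sets of Ahr itself were slightly higher (log2 0.32 and 0.44). Which part of the transcript they read, and whether the transgene holds it, is not known here, so they do not check the label. The median of 7 measured AhR pathway components, Ahr included, was -0.16, inside the central 95% of random lists. Its members ran from Ahr down to the coregulator Nrip1 (-0.53) and the chaperone Hsp90aa1 (-0.42), with Ncoa1 at 0.07.

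**Figure D2:**
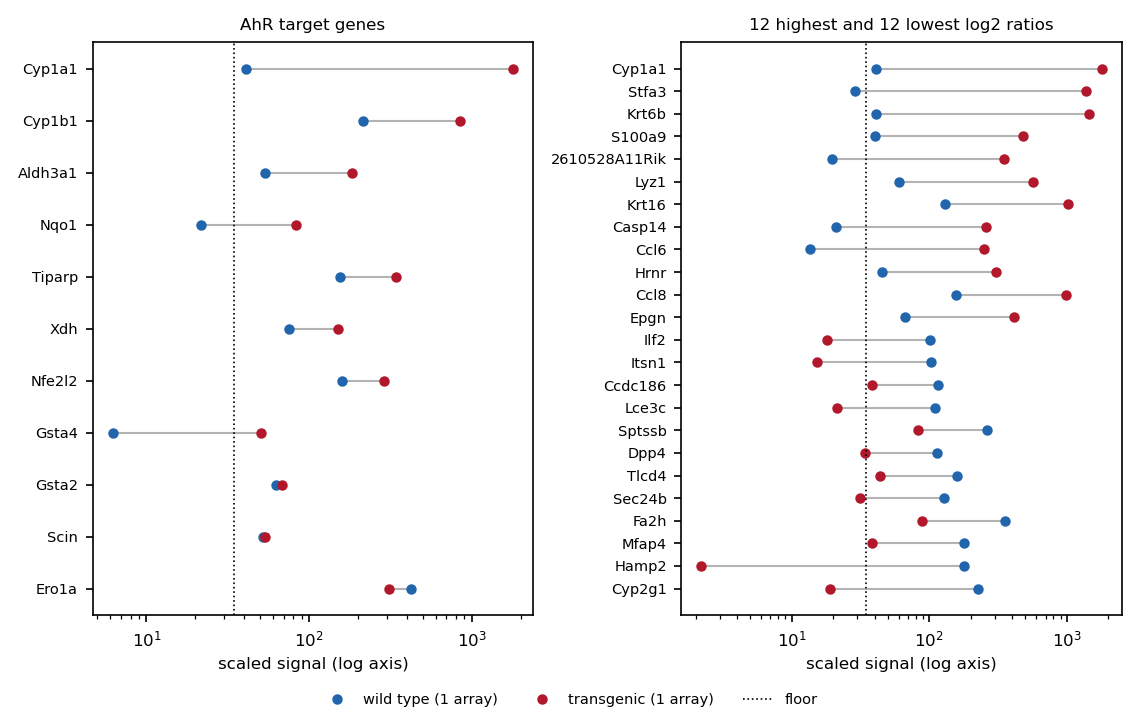
Scaled signal of single genes (log axis) on the wild-type array (blue) and on the transgenic array (red), 1 array each; the dotted line is the floor of 34.7. The left panel holds the 11 measured AhR target genes, from Cyp1a1 at 40.8 and 1802 to Ero1a at 426 and 311, and the right panel the 12 highest and the 12 lowest log2 ratios of all genes.

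Of 20 measured genes listed for hyperproliferation and alarm of keratinocytes, as in wounded and inflamed epidermis, 12 were at least 2-fold higher and none was at least 2-fold lower. The median log2 ratio was 1.22, against -0.19 to 0.12 for random lists. The list is not exclusive to keratinocytes, since it holds S100a9, which neutrophils express too. Macrophage (1.44) and granulocyte (0.61) medians were also higher on this array, and how much of the list's rise came from such cells was not tested. Beyond Stfa3, Krt6b, S100a9, Krt16 and Epgn, the list ended with Defb1, a constitutive beta-defensin (0.08), and Tgfa, another ligand of the epidermal growth factor receptor (-0.30). The cornified envelope and late differentiation genes diverged. Of 32 measured members, 12 were at least 2-fold higher and 2 at least 2-fold lower, with a median of 0.56 (random lists -0.14 to 0.11). Casp14 and Hrnr led the list. In the Lce1 family, which encodes late cornified envelope proteins, 7 of 9 genes were at least 2-fold higher, with a median of 1.27. Without probe sets that can cross-hybridise it was 4 of 6, with a median of 1.19. Names were the only guide to this, and probe sequences were not checked. Among the unmarked probe sets, those of Lce1b (977.1 against 421.4) and Lce1a2 (970.4 against 430.5), both outside the naming rule, read nearly alike. The Lce1 genes may therefore not be separate readings. By contrast Ivl, the gene of the envelope scaffold protein involucrin, was 2.83-fold lower (42.9 against 121), and Lce3c was lower too. The 6 measured genes of the Sprr family, also in this list, had a median of -0.60. Among those 6, 1 was at least 2-fold higher and none at least 2-fold lower. Without probe sets that can cross-hybridise the Sprr median was -0.56 over 5 genes. With the floor at the 60th percentile Ivl was at -0.78 and Lce3c at -0.64.

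Many of these genes lie side by side in the epidermal differentiation complex. Of the 36 measured genes between S100a1 and S100a10 there, 13 (36.1%) were at least 2-fold higher and 2 (5.6%) at least 2-fold lower. Among the 8858 other measured genes, 2.13% were higher and 1.07% lower by that much. Without probe sets that can cross-hybridise 9 of 30 genes of the complex were higher and 1 lower by that much, and with the floor at the 60th percentile 12 of 30 were higher and none lower.

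The 17 basal keratinocyte genes had a median of 0.56 (random lists -0.20 to 0.15), with 14 above 0. Itgb4, an integrin of hemidesmosomes, was 2.02-fold higher and the hyaluronan receptor Cd44 had a log2 ratio of 0.83. Krt15, a keratin of basal cells and of the hair follicle bulge, was 2.69-fold lower (317 against 851), and Trp63, the gene of the epithelial regulator p63, had a log2 ratio of -0.29. The 15 suprabasal genes had a median of 0.19 (random lists -0.14 to 0.17) with 2 bright outliers. This median lay inside the random range with lowess centring (0.14) and without suffixed probe sets (0.19 over 11 genes). Krt1, a major keratin of the spinous layer, read 2992 against 489 (6.12-fold higher), and Calm4, a calcium-binding protein of differentiating keratinocytes, 3440 against 724 (4.75-fold higher). Dsc2, a desmosomal cadherin gene, had a log2 ratio of -1.32 and Ppl, the gene of periplakin, of -0.33. Proliferation genes stayed near equality. Of 34 measured cell cycle genes none was at least 2-fold higher and 1 was at least 2-fold lower, Cenpa, a centromeric histone (2.35-fold). The median was -0.07, at percentile 34.9 of the random lists. Cdk1, the kinase of mitotic entry, had a log2 ratio of 0.46, Pcna, the sliding clamp of DNA replication, 0.32, and Plk4, a centriole kinase, -0.71.

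Inflammatory cytokine and chemokine genes were higher as a group, 8 of 22 measured members by at least 2-fold and none lower by that much. The median was 0.72 (random lists -0.21 to 0.11). Ccl6 and Ccl8 led the list, and the lowest members were Ccl22 (-0.10) and the interleukin-1 receptor antagonist gene Il1rn (-0.09). In 7 of the 22 members 1 array lay at the floor, so their ratios are bounds.

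The medians of the leukocyte marker lists ran from -0.08 to 1.44. Macrophage genes had the highest median of the 32 lists, 1.44 (random lists -0.21 to 0.11), with 15 of 22 measured members at least 2-fold higher and none at least 2-fold lower. After Lyz1, C1qa, a chain of complement C1q, was highest (306 against 50.9, 6.01-fold higher), and all 3 C1q genes were at least 2-fold higher with a median of 2.09. Fcgr1, a high-affinity antibody receptor, had a log2 ratio of at least 0.18 and Msr1, a scavenger receptor, of -0.29. Of these 22 macrophage genes, 18 were above the floor in wild-type skin too, and no gene of any list was shared with another list. The 9 mast cell genes had a median of 0.80 (random lists -0.34 to 0.23). The proteases Mcpt2 and Mcpt4 were 2.82-fold and 2.35-fold higher, while the stem cell factor receptor gene Kit (-0.46) and the antibody receptor subunit gene Ms4a2 (-0.15) were not. The 11 Langerhans and dendritic cell genes had a median of 0.64 (random lists -0.24 to 0.20). There the MHC class II genes H2-Ab1 (3.35-fold) and H2-Aa (2.61-fold) were highest and Cd1d1 (-0.26) and Fscn1 (-0.17) lowest. The probe sets of H2-Aa can all cross-hybridise, and the 1 probe set of H2-Ab1 without such a mark gave 0.62. The MHC class II set held 5 genes of the list, counting Cd74, the gene of the invariant chain, which is outside the naming rule. Of these 3 were at least 2-fold higher. Without probe sets that can cross-hybridise 1 of 4 was, Cd74 (1.22), with a median of 0.93. The median of the whole list was 0.39 without suffixed probe sets. Cd207, the Langerhans cell lectin gene, lay below the floor on both arrays. Over 5 granulocyte genes the median was 0.61, led by Hp, the gene of haptoglobin (3.92-fold), and Fpr2 (0.87) and ending with Mpo (0.01) and Csf3r (at least 0.12). The 8 measured genes of type 2 immunity had a median of 0.52 (0.27 over 7 genes without suffixed probe sets). Clec10a was 2.07-fold higher and the matricellular protein gene Postn had a log2 ratio of 0.82, but the arginase gene Arg1 was at -0.83 and the transcription factor gene Gata3 at -0.07. T cell and B cell lists lay inside the random range, with medians of -0.08 over 6 genes and -0.01 over 5. None of the 5 genes of CD3 chains, CD4 and CD8 was above the floor on either array, so these lists say little about lymphocytes. The highest measured T cell genes, Thy1 (0.80) and Zap70 (0.74), stood beside Icos (-0.42) and Ctla4 (at most -0.16). The other probe set of Zap70 lay below the floor on both arrays (4.8 and 9.5). Among B cell genes Ms4a1 was at least 0.44, Ighm 0.01, Blk -0.19 and Vpreb3 -0.32. The T cell median was 0.77, outside the random range, with the floor at the 60th percentile, where 2 genes were measured.

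**Figure D3:**
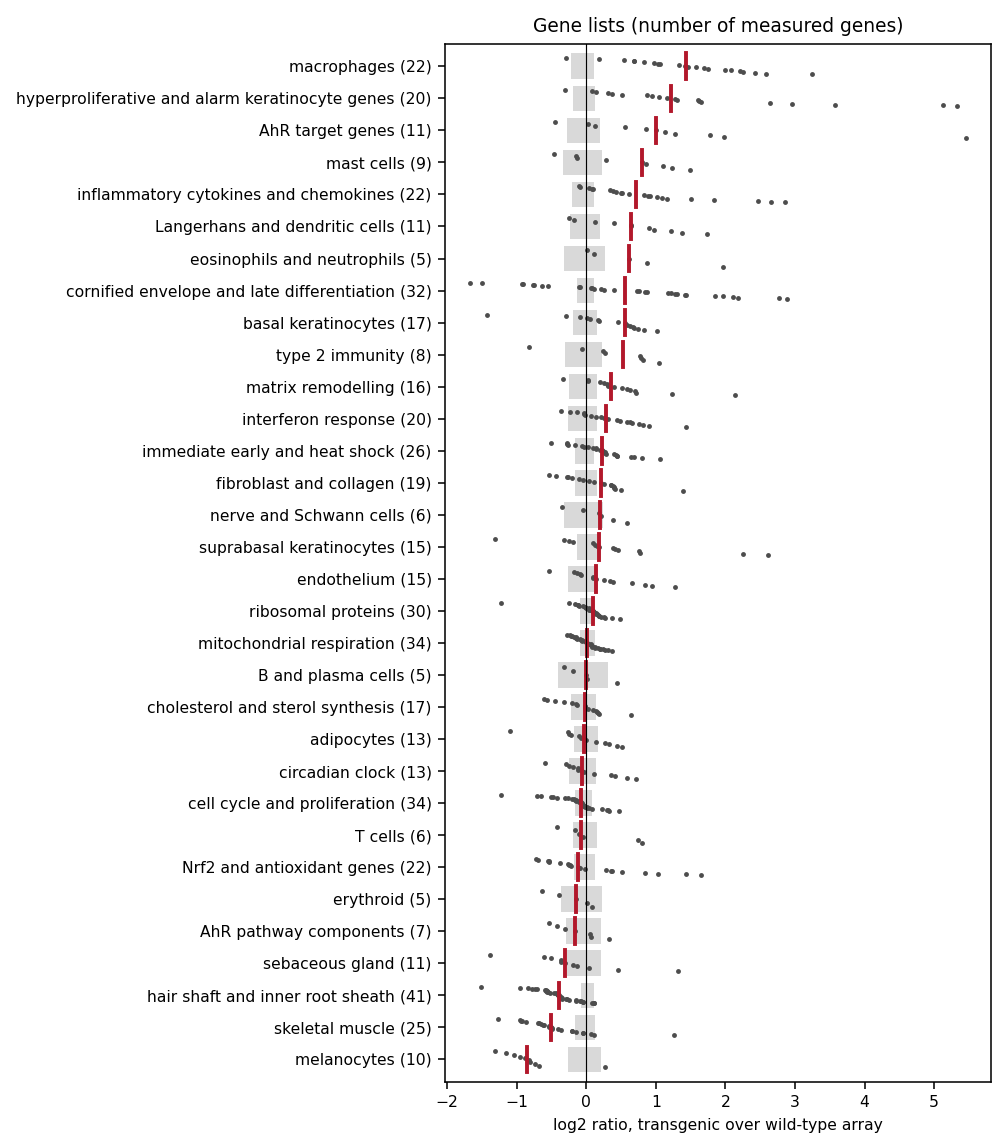
Log2 ratio of transgenic over wild-type signal for each measured gene (points) of the 32 lists, with the number of measured genes in brackets, the median of each list (red bar) and the central 95% of the medians of 10000 random lists of the same size and brightness (grey box). Macrophage genes have the highest median, 1.44, and melanocyte genes the lowest, -0.85.

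Hair, pigment and muscle genes were lower. Of 41 hair shaft and inner root sheath genes 38 lay below 0, with a median of -0.40 (random lists -0.07 to 0.12), though only Krt84, a hair keratin, was at least 2-fold lower (199 against 565). Krtap5-2, a keratin-associated protein gene, had a log2 ratio of -0.95, and the highest members were Krtap13 (0.12) and Krtap6-3 (0.11). The 10 melanocyte genes had the lowest median of all lists, -0.85 (random lists -0.26 to 0.22), with 9 below 0. The melanin synthesis genes Tyr and Tyrp1 were 2.49-fold and 2.22-fold lower, Gpr143, the gene of a melanosome receptor, had a log2 ratio of at most -0.69, and Rab38, a melanosome transport gene, lay above 0 at 0.27. Tyr was at -0.90 without suffixed probe sets. Of 25 skeletal muscle genes 22 lay below 0, with a median of -0.51 (random lists -0.16 to 0.12). Myh8, the perinatal myosin heavy chain gene, was at least 2.41-fold lower. The intermediate filament gene Des had a log2 ratio of -0.95 by its brighter probe set and 0.22 by the other. Myoz1 was at 0.11, and Tpm2, a tropomyosin gene, was 2.40-fold higher but had a log2 ratio of -0.17 without suffixed probe sets. The 11 sebaceous gland genes had a median of -0.30, just below the random range of -0.27 to 0.21. It lay inside that range with the floor at the 60th percentile (-0.19) and with the mean over a gene's probe sets (-0.21). Scd3, a fatty acid desaturase of sebocytes, was 2.61-fold lower and Acaca had a log2 ratio of at most -0.61, while Mgst2 was at least 1.32 and Acsbg1 0.45.

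In the lists of matrix, interferon, immediate early and fibroblast genes few members differed by 2-fold, 2, 1, 1 and 1 of them higher by that much. The 16 matrix remodelling genes had a median of 0.36 (random lists -0.25 to 0.16), led by the metalloprotease inhibitor gene Timp1 (4.38-fold) and Tnc, the gene of the wound matrix protein tenascin C (2.36-fold), with Timp3 at 0.03 and Plat at -0.34. The 20 interferon response genes had a median of 0.28 (random lists -0.26 to 0.15), but of 0.14, inside the random range, over 15 genes without suffixed probe sets. Psmb8, an immunoproteasome subunit gene, was at least 2.70-fold higher and Gbp2 at least 0.90, but Oas3 (-0.37) and Oasl1 (-0.23) were lower. The 26 immediate early and heat shock genes had a median of 0.23 (random lists -0.16 to 0.11), with Fos 2.09-fold higher, Ier3 at 0.80, Hspe1 at -0.28 and Egr3 at -0.50. The 19 fibroblast genes had a median of 0.21 (random lists -0.16 to 0.16). With the mean over a gene's probe sets the fibroblast median was 0.14, inside the random range. Pdgfra was 2.63-fold higher (a log2 ratio of 0.79 with that mean) and Dcn at 0.49, whereas Mfap5 was at -0.44 and the collagen gene Col1a1 gave -0.54 by 1 probe set and 0.41 by another.

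The medians of the remaining lists lay inside the central 95% of their random lists. They were 0.14 for 15 endothelial genes, 0.19 for 6 nerve and Schwann cell genes, -0.03 for 13 fat cell genes, -0.15 for 5 erythroid genes, 0.09 for 30 ribosomal protein genes, 0.01 for 34 genes of mitochondrial respiration, -0.07 for 13 circadian clock genes and -0.02 for 17 genes of sterol synthesis. The 22 Nrf2 and antioxidant genes had a median of -0.11 although 3 of them were at least 2-fold higher, among them the glutathione peroxidase genes Gpx2 (3.15-fold) and Gpx3 (2.71-fold). Gsr (-0.73) and Txnrd1 (-0.70), which regenerate reduced glutathione and thioredoxin, were lower. The endothelial median lay above its random range under 4 alternatives (0.36 with the floor at the 20th percentile, 0.27 with a pseudocount, 0.25 without suffixed probe sets and 0.14 with the mean over probe sets), and the Nrf2 median below it without probe sets that can cross-hybridise (-0.23). Single members stood out in lists near 0. Plvap, an endothelial diaphragm gene, was at least 2.42-fold higher, the desaturase gene Scd1 was 2.14-fold lower (679 against 1456), and Rps27 was 2.33-fold lower while the other 29 measured genes of the ribosomal protein list lay within 2-fold.

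Measures of RNA quality were close. The ratio of the 3' to the 5' control signal of beta-actin was 1.35 on the transgenic and 1.27 on the wild-type array, and that of Gapdh 0.776 and 0.804. Xist, transcribed from the inactive X chromosome of females, read 1149 and 1246, and the Y-linked genes Kdm5d (35.1 and 42.1), Eif2s3y (21.6 and 39.3) and Uty (26.4 and 30.0) lay near or below the floor. The technical SD of a log2 ratio was 0.256, a spread that leaves out differences between animals. It is the SD of the difference between 2 probe sets of a gene, divided by the square root of 2. It was taken over 2535 genes with 2 probe sets above the floor on both arrays. Of 48 higher genes with a second measured probe set, that set was above 0 in 45 and at least 2-fold higher in 20; of 36 lower genes it was below 0 in 32 and at least 2-fold lower in 8.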

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

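All tests in this part were chosen after the results they bear on had been seen. Probe sets without a single gene name stayed out of the comparison, yet 30 of these 2246 probe sets were at least 2-fold higher on the transgenic array and 8 were at least 2-fold lower. Among those with no gene in the annotation, the highest was at least 5.99-fold higher (208 against a wild-type signal of 31.6, below the floor). Among those with several genes, the highest was 17.9-fold higher (2627 against 147).

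Hair, pigment cell and muscle genes were lower together. A smaller share of hair follicles in the transgenic sample would lower pigment cell genes, which at this age are expressed largely inside follicles, by as much as hair genes. Against the 10 hair genes no brighter than the melanocyte genes, the melanocyte median was lower by a difference of -0.35 (95% interval -0.60 to -0.06). Against all 41 hair genes, the comparison made first, the difference was -0.455. Both list medians had been seen before, so a gap in this direction was known beforehand. Whether follicle share is the whole cause for the pigment genes therefore stays undecided. Bright hair genes may be compressed, since their log2 ratios lay closer to 0 at higher signal (Spearman's rho = 0.42 across 41 genes, 0.08 to 0.68), so their true difference could be larger. Less muscle in the transgenic sample may account for the muscle genes, whose median was -0.51 (-0.65 to -0.21 over 25 genes), and an effect of the genotype on follicles, pigment cells or muscle stays open and untested.

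Macrophage genes had the highest list median, 1.44 (1.10 to 1.66 over the alternatives, which overlaps the 1.04 to 1.31 of the hyperproliferation and alarm genes). A smaller share of other tissue would raise the other lists alike. The macrophage median exceeded that of endothelial, fibroblast and fat cell genes by 1.32 (95% interval 0.79 to 1.83). This gap was known beforehand, since the lists compared were picked after their medians had been seen. Of the lists left out, basal keratinocyte (0.56) and mast cell genes (0.80) were higher and hair (-0.40) and muscle genes (-0.51) lower. The share of other tissue therefore stays undecided. A difference of this size in RNA integrity or hybridisation across the arrays is argued against. The actin and Gapdh ratios bear on integrity and the spike-in controls on hybridisation. Among them the log2 difference of greatest size was 0.29, below the lower bound of the macrophage median, 0.97. The dimmest spike-in read below the floor, so differences particular to the dimmest genes are not covered. The macrophage median exceeded that of T and B cell genes by 1.49 (0.886 to 2.004), but a rise of macrophages and a rise of all leukocytes cannot be told apart, since 11 of 32 listed T and B cell genes were measured, below a minimum of 20 set after the result was seen, and with the floor at the 60th percentile, which leaves 5, the interval was -0.06 to 1.95. More macrophages, or more of these transcripts per macrophage, may follow from the transgene, from the litter or from the health of the animal sampled, and with 1 array per genotype none of these was tested.

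Late differentiation genes went both ways. Cross-hybridisation between similar probe sets was tested by leaving out those whose names mark it: 13 of the 27 members then measured lay above 0 by more than 2 technical SD (random lists 0 to 5), which argues against it as the whole cause for the higher members. Probe sets without the mark were not checked by sequence. For the lower members cross-hybridisation stays narrowly open, since 6 then lay below 0 by that much (8 of 32 with all probe sets). That reaches but does not pass the upper limit of random lists (0 to 6). A larger share of keratinocytes would move the members by about the basal median (0.56). Of the 32, 22 lay more than 2 technical SD (0.512) from it, 12 above and 10 below. Random lists had 2 to 10 in their central 95%, counted about their own medians. The 12 are the members at least 2-fold higher and the 10 those below 0, so the count restates the pattern. It shows that a single common shift does not describe the list, but it is no separate test of the share of keratinocytes. A shift within the late differentiation programme, with Hrnr, Casp14 and Lce1 genes higher, may contribute, a hypothesis found on these 2 arrays, with the lower members left open.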

How the results depend on the processing

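All alternatives but 1, leaving out probe sets that can cross-hybridise, were chosen before the data were examined. Scaling mattered little: the values as deposited, median centring, quantile normalization and lowess centring gave 202 to 234 higher and 79 to 97 lower genes, against 202 and 97, and the share of calls that were higher ran from 60.4% to 74.8% over all normalizations, floors and probe set rules (67.6% in the main setting). The counts followed the floor and the limit by construction. The floor at the 20th percentile gave 392 higher and 257 lower genes and that at the 60th 123 and 45; a limit of 1.5-fold gave 605 and 567 and one of 3-fold 61 and 9. The medians of the AhR target, late differentiation and cytokine lists stayed above 0 under all 10 alternatives that apply to them and that of the cell cycle list below 0 (-0.09 to -0.02). Some medians moved by more than their technical spread. AhR target genes moved to 1.31 with the floor at the 20th percentile and 0.88 without probe sets that can cross-hybridise. Late differentiation moved to 0.80 with the floor at the 20th percentile, 0.86 with that at the 60th and 0.78 with a pseudocount. It moved to 0.50 with the mean over probe sets, 0.48 without suffixed probe sets and 0.40 without those that can cross-hybridise. Cytokines moved to 0.80 with lowess centring, 0.81 with the floor at the 60th percentile and 0.83 without suffixed probe sets. Of 280 values for the medians of the other 28 lists 38 moved as much and none of a list outside its random range changed sign; mast cell genes ran from 0.54 to 1.10, Langerhans and dendritic cell genes from 0.39 to 0.80, type 2 immunity from 0.27 to 0.58, basal genes from 0.38 to 0.61 and immediate early genes from 0.16 to 0.28. Tpm2 reversed, from 1.27 to -0.17 without suffixed probe sets. The cause of these shifts was not tested. Dim genes depend on the floor: at the 60th percentile the calls of Sec24b (-0.87), Itsn1 (-0.54), Ilf2 (-0.52), Dpp4 (-0.69), Ccdc186 (-0.70), Clec10a (0.59), Psmb8 (0.41), Mgst2 (0.30), Plvap (0.25), Myh8 (-0.25), Cenpa (-0.95) and Rps27 (-0.96) ended as well as those already named. Averaging over probe sets ended those of Pdgfra (0.79), Tpm2 (0.38), Sec24b (-0.81), Itsn1 (-0.68) and Ilf2 (-0.65), and the pseudocount those of Itgb4 (0.89), Clec10a (0.86) and Fos (0.96). Leaving out suffixed probe sets ended those of Dsc2 (-0.94), Tiparp (0.88), Tyr (-0.90) and Lyz1 (0.04), and left Hamp2 and Itsn1 with probe sets below the floor; leaving out only those that can cross-hybridise ended those of Tiparp, Lyz1, Hamp2 and Itsn1 in the same way and that of H2-Ab1 (0.62). Of 154 named genes 21 have no probe set without a suffix and so no value there, 9 of them called: Cyp1a1, Fa2h, Lce3c, Cenpa, Itgb4, Psmb8, Mcpt4, H2-Ab1 and H2-Aa; Lce3c and H2-Aa are the 2 called genes whose probe sets can all cross-hybridise. For Cyp1a1, under the other alternatives its log2 ratio ran from 4.67 to 5.52. The medians of the AhR pathway, T cell, B cell, fat cell, nerve, mitochondrial, circadian and sterol lists changed sign under at least 1 alternative. No paired analysis was possible because each group has 1 array.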

Other observations

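The genes in this part were chosen after their values were seen, and so were the themes of its 4 lists. Klk6, a secreted serine protease of the epidermis, was 5.10-fold higher (880 against 173), and Lyve1, a hyaluronan receptor of lymphatic vessels and some macrophages, at least 3.52-fold. Among cytokine genes Ccl9 was 5.56-fold higher, Ccl20, a chemokine that attracts dendritic cells and lymphocytes, at least 3.56-fold, and the alarmin Il33 at least 2.83-fold. Kitl, the gene of stem cell factor, a growth factor of melanocytes and mast cells, was 2.21-fold lower (101 against 223). With the floor at the 60th percentile Lyve1 (0.79), Ccl20 (0.81) and Il33 (0.48) were under a 2-fold difference, as was Kitl (-0.82) with the mean over probe sets. Artn, the gene of the neurotrophic factor artemin, lay below the floor on both arrays (29.2 and 3.7). The floor at the 20th percentile, 11.9, lies between these signals, so this reading depends on the floor.

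Several higher or lower genes shared a function, and 4 lists of further genes of those functions, whose own values had not been seen, were then examined with the same random lists. Lipid synthesis genes seen at first were lower, among them Fa2h, Sptssb and the fatty acid elongase gene Elovl6 (2.63-fold). The 34 further measured genes had a median of -0.13, at percentile 5.84, inside the central 95%, so a lower level of lipid synthesis genes in general stays undecided. For retinoid metabolism, Adh7 and Crabp2 had been 3.91-fold and 2.80-fold higher. Rarres2 (4.19-fold higher) had been counted with them, although it is named for its response to retinoids and is not a gene of their metabolism. The 18 further genes had a median of 0.01, at percentile 78.3, which leaves a general difference undecided too. For complement, after the C1q genes, the 13 further genes had a median of 0.28, at percentile 99.7, above the central 95%. C1ra was at least 2.24-fold higher (0.13 with the floor at the 60th percentile) but Clu was at -0.76. The list holds genes of myeloid cells such as Itgb2 (at least 0.78) and C3ar1 (0.28), and the macrophage median was 1.44, so complement genes beyond C1q may be higher on this transgenic array along with macrophage genes, from which they were not separated. For the glucocorticoid response, where Tsc22d3, Cebpd, Thbd and Pdk4 had been 3.75-fold, 3.01-fold, 3.03-fold and 2.61-fold higher, the 24 further genes had a median of 0.11, at percentile 97.4, just inside the central 95%. That list first held Pnpla2, whose value had been seen among the fat cell genes; with it the percentile was 99.9, so 1 gene decides on which side of the limit this list falls, and a glucocorticoid or stress response in the transgenic animal stays an undecided hypothesis. These 4 lists are 1 family, and no allowance was made for looking at 4.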
